A study of Mus musculus with 4 samples.

How the data were processed

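RNA from the dissected cerebella of 4 mice, 2 heterozygous for an Arid1b knockout and 2 wild type littermates, with 1 male and 1 female of each genotype, was made into strand-specific poly(A) libraries and sequenced together in 1 lane as single-end reads of 100 bases, per the labels' protocols. The deposited table holds raw counts of reads per gene symbol, with 1 column per library and no rows for unassigned reads. STAR, featureCounts, FastQC and edgeR and the genome build mm9 are named in the submitters' processing notes, without versions, settings or order, and the strand setting of the counting is not given in the sources used here. Reads from overlapping or antisense genes could therefore be split in an unknown way. Mitochondrially encoded genes were not analysed here, since their list had 0 members in the table.

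Genotype and sex were taken from the labels, and the groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The replicate numbers only name libraries, with 1 for the male and 2 for the female of each genotype, so no pairing by number was made. Genes with enough counts were kept with edgeR's filterByExpr by genotype, which left 15117 of 24015 genes holding 99.9% of the counts. Library sizes were scaled by TMM, whose factors lay between 0.999 and 1.00. The fit was edgeR 4.0.16 in R 4.3.3, a robust quasi-likelihood fit with sex and genotype as terms and 1 residual degree of freedom, moderated across genes (median prior degrees of freedom 10.6, common biological coefficient of variation 11.5%). P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes at 0.05, and the standard error of a log2 fold change was its size divided by the square root of the F statistic. Means per genotype are given as CPM ± SD over 2 libraries. With 3 counts as the floor, the totals of 15950899 to 20616219 counts allow a level of 0.146 to 0.188 CPM for a gene with no count, which covers counting error only.

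The sex contrast came from the same fit. The difference of the genotype effect between the sexes was the product of both codes in a fit with genotype and that product. Within each sex, log2 ratios of the single libraries were taken with a prior count of 2 and have no test. Of 33 gene lists, 32 had at least 4 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera's estimated correlation and with fry beside it, adjusted over the 32 lists, and members were also adjusted over the list alone. With an estimated correlation 0 of the lists were called. With fry 0 were called by its directional test, which asks whether a list's genes move one way on balance, and 0 by its mixed test. With 1 residual degree of freedom, the estimated correlation gave most lists an adjusted p of 0.862, whether or not camera called them. It therefore cannot tell such lists apart. Named genes were Arid1b, the genes past the threshold and alike in both sexes (up to 15 per direction with the largest changes), genes of smallest p to fill each direction to 10, up to 4 members of smallest p per list, and for sex the members of both sex lists and the 5 genes of smallest p outside them, with a mean of at least 1 CPM unless in a list.

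The alternatives were DESeq2 1.42.0, edgeR's likelihood ratio test, limma-voom, DESeq2's size factors, library totals, no low-count filter, a stricter filter of 1 CPM in at least 2 libraries, no sex term, an adjusted p of 0.1, other prior counts (0.5 and 5), a minimum mean of 10 CPM, and leaving out each library in turn, where genotype is the only term, so that sex is partly mixed with genotype, and the lone library of a genotype is assumed to vary like the others. A fit that removed the trend with transcript length and GC content was added after seeing the data, with lengths of the longest annotated transcript for 99.3% of tested genes. A correlation under an alternative was called unchanged only within its Fisher confidence interval, a bound that replaced a looser one after the values were seen. Lists of pituitary, skeletal muscle, posterior Hox, projection neuron and midbrain genes were added after seeing the data and before their sums were computed.

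Scripts were tested on simulated data before use. In 3 simulations of the heterozygote against wild type comparison, each with 200 changed genes, about 14962 genes were tested, and the fit with sex and genotype recovered 51.2% of 1.5-fold, 76.1% of 2-fold and 99.0% of 4-fold changes, all with the right sign, with 3.83% of calls false. With no change simulated over 15117 genes, edgeR, DESeq2 and limma-voom gave 0 calls. A simulated list of 20 genes shifted by -0.35 on the log2 scale was called by camera (adjusted p = 2.06e-13) and missed with an estimated correlation (adjusted p = 0.938), and 0 of 20 unshifted lists were called. The simulated genes were drawn independently of each other. These simulations therefore cannot show how camera at the preset correlation behaves for lists whose genes vary together. Apart from the set changes, every library was drawn from the same mean per gene, without a sex effect or a deviating library. The shares recovered and false may therefore not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.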

Results

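Arid1b encodes a DNA-binding subunit of the BAF complex, a machine that moves nucleosomes, and the study asked how losing 1 copy of the gene changes transcription in the adult mouse cerebellum. Cerebella were dissected from heterozygous knockout mice and wild type littermates of the C57BL/6N substrain at 140 to 150 days of age, and messenger RNA was sequenced. The 4 libraries were 1 male and 1 female of each genotype, so that each genotype had 2 libraries and sex was balanced between them. The table held 24015 genes. The total count was 20287016 in the male heterozygote, 16453759 in the male wild type, 15950899 in the female heterozygote and 20616219 in the female wild type. The labels describe the libraries as mice of a genotype and sex without naming individual animals, so p-values measure the spread between these libraries.

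Arid1b itself was lower in both heterozygotes than in both wild types. It stood at 53.0 CPM (counts scaled to the library total) in the male heterozygote and 55.9 in the female heterozygote, against 69.9 in the male wild type and 70.9 in the female wild type. The mean was 54.4 ± 2.06 CPM (SD, n = 2) in the heterozygotes and 70.4 ± 0.704 (SD, n = 2) in the wild types, a log2 fold change of -0.37 ± 0.11 (SE) or a 0.773-fold level. That change did not pass the test over all genes (edgeR quasi-likelihood test, adjusted p = 0.243), nor over the BAF subunits alone (adjusted p = 0.0932). The Arid1b log2 fold change was -0.33 without the male heterozygote and -0.42 without the female heterozygote. It was -0.38 without the male wild type and -0.36 without the female wild type. The counts cover the whole gene, and the deleted part is not given in the sources used here, so they show the transcript level and not the deletion.

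Of the 28 BAF subunits, 7 were higher and 21 lower in the heterozygotes, with a median log2 fold change of -0.04, and none passed the test singly. Smarcd2, a core-module subunit, had a log2 fold change of -0.36 ± 0.10 (SE), which was -0.16 without the male heterozygote, -0.14 without the female wild type, -0.56 without the male wild type and -0.61 without the female heterozygote. Arid2, the DNA-binding subunit of the related PBAF complex, had -0.24 ± 0.13 (SE). As a set, the subunits did not stand apart from other genes (camera, adjusted p = 0.0983). The median of the subunits was -0.01 without the female wild type and -0.06 without the female heterozygote. The 14 tested genes that flank Arid1b had a median of 0.02, with 8 higher and 6 lower (camera, adjusted p = 0.803). Among them were Synj2 at 0.27 ± 0.13 (SE) and Zdhhc14 at -0.25 ± 0.12 (SE). The median of the flanking genes was -0.05 without the female heterozygote and -0.02 without the female wild type. It was -0.00267 without the male heterozygote and 0.01 without the male wild type.

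Between the genotypes, 3 genes rose in the heterozygotes and 0 fell past an adjusted p of 0.05. Slc6a5, the glycine transporter of inhibitory glycinergic neurons, rose from 8.61 ± 4.16 to 22.3 ± 6.96 CPM (mean ± SD, n = 2 each), a log2 fold change of 1.42 ± 0.18 (SE). Th, tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, rose from 25.1 ± 7.94 to 54.7 ± 4.39 CPM (mean ± SD, n = 2 each), a log2 fold change of 1.15 ± 0.15 (SE). Prl, the pituitary hormone prolactin, had a fitted log2 fold change of 3.33 ± 0.43 (SE), but its 310 counts in the female heterozygote stood against 34 in the female wild type, 6 in the male heterozygote and 2 in the male wild type. All of these had an adjusted p of 0.0473 in edgeR's quasi-likelihood test. Dbh and Slc6a3, genes of brainstem and midbrain neurons chosen after their values were seen, ordered the 4 libraries as Slc6a5 and Th did. Hoxa5 and Slc18a2 did not. For the Slc6a5 and Th calls, more brainstem or midbrain in the heterozygote pieces was not tested apart from an effect of the genotype. Slc6a5 and Th were higher in the heterozygote of each sex, with log2 ratios of 1.23 and 0.91 in males and 1.60 and 1.40 in females. The difference of these ratios between the sexes is the only residual of the fit, so a small p favours such agreement. The log2 fold changes of Slc6a5 and Th were 1.02 and 1.04 without the male heterozygote, and 1.66 and 1.20 without the female heterozygote. They were 1.98 and 1.49 without the male wild type, and 0.96 and 0.83 without the female wild type. In such fits the genotype that keeps 2 libraries alone sets the spread. A call kept or lost there depends on how alike that pair is and does not measure how firm the change is. Prl ran from -1.62 to 6.23 with a library left out.

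**Figure D1:**
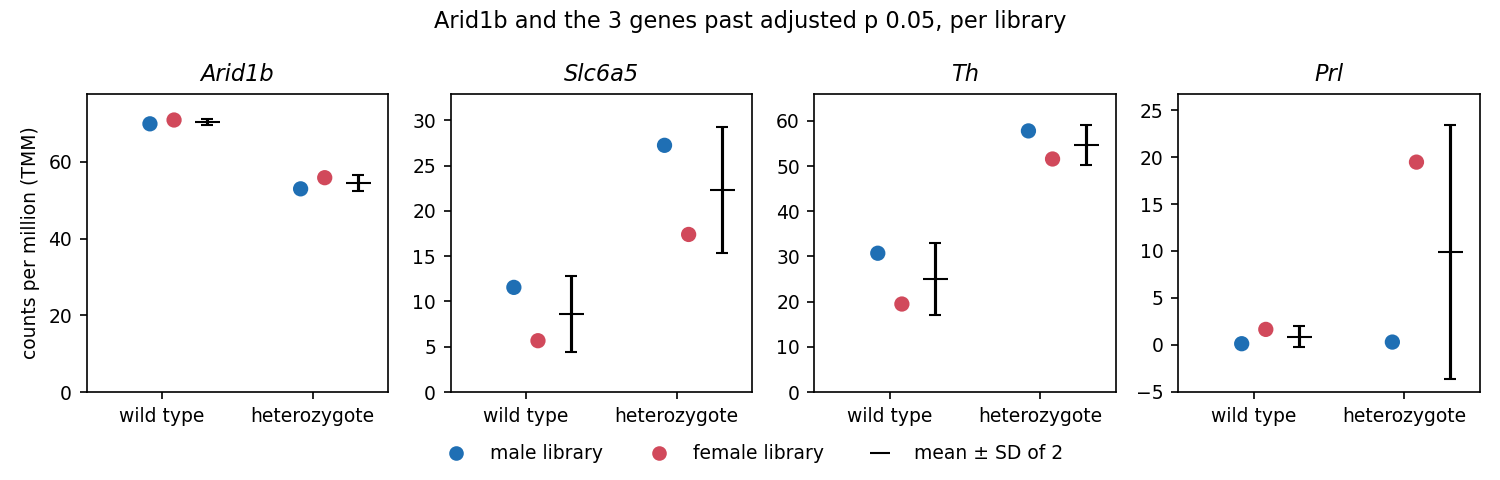
Normalised CPM (vertical axes, a separate linear scale per gene) of Arid1b, Slc6a5, Th and Prl in the 2 wild type and 2 heterozygous libraries, blue for males and red for females, with the mean ± SD of each genotype beside them. Slc6a5 lies at 17.4 and 27.2 in the heterozygotes against 5.67 and 11.6 in the wild types, whereas Prl is high in the female heterozygote alone (19.5).

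The genes next in order of p did not pass, and their values are given as measured. On the higher side, Sst, the neuropeptide somatostatin, stood at 98.2 ± 0.496 CPM in the heterozygotes and 59.1 ± 3.92 in the wild types (mean ± SD, n = 2 each), a log2 fold change of 0.73 ± 0.11 (SE). Spp1, the secreted phosphoprotein osteopontin, had 0.68 ± 0.10 (SE), and both had an adjusted p of 0.071. Crhbp, the binding protein of corticotropin-releasing hormone, had the largest ratio of these genes, 1.56 ± 0.29 (SE). Nnat (0.79), Arhgdig (0.67), Limk1 (0.55), which encodes a kinase that acts on actin turnover through cofilin, and Nefl (0.53), the light neurofilament chain, followed, with adjusted p from 0.13 to 0.135. On the lower side, Sycp1, a protein of the meiotic synaptonemal complex, stood at 5.08 ± 0.70 CPM in the heterozygotes and 14.1 ± 0.379 in the wild types (mean ± SD, n = 2 each), a log2 fold change of -1.47 ± 0.22 (SE). Alas2, the haem synthesis enzyme of red cell precursors, had -1.33 ± 0.20 (SE), and both again had an adjusted p of 0.071. Dnah11, an axonemal dynein heavy chain, stood at 10.5 ± 1.36 CPM in the heterozygotes and 21.2 ± 3.78 in the wild types (mean ± SD, n = 2 each). Malat1 (-0.69), a nuclear long non-coding RNA, AI414108 (-0.62), Paxbp1 (-0.62), Camk4 (-0.59), a calcium-dependent kinase of granule cells, Fat2 (-0.58), a granule cell cadherin, Nrep (-0.58) and Reln (-0.56), the secreted glycoprotein reelin, all had an adjusted p of 0.13. All of the genes named so far in this paragraph lay on the same side in both sexes. Their choice by small p favours such agreement, because the residual of the fit is the difference between the sexes. It is therefore no separate support. Without the male heterozygote Malat1 was at -0.32 and Spp1 at 0.44, and without the female heterozygote Malat1 was at -1.09. Without the female wild type Nnat was at 0.46 and Paxbp1 at -0.40. Malat1 stood at 211 CPM in the male heterozygote, 355 in the female heterozygote, 397 in the male wild type and 492 in the female wild type. Rn45s, the ribosomal RNA precursor, took 0.183%, 0.226%, 0.242% and 0.323% of counts in the same order. A difference in library make-up was not tested apart from genotype for Malat1.

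At an unadjusted p under 0.05 the genotype term took in 1766 of the 15117 tested genes, 789 higher and 977 lower, where 755.85 would be expected by chance. DESeq2's size factors gave 5 higher and 2 lower genes past the adjusted threshold, and library totals alone gave 5 higher and 8 lower. The count of 3 fell to 0 without the sex term, under a stricter low-count filter and without the male heterozygote, rose to 34 with DESeq2, 204 with the likelihood ratio test and 553 with no filter, and was 2730 without the male wild type and 658 without the female wild type. Without the female heterozygote it was again 3, but these were Ckm, Acta1 and Myl1, genes of skeletal muscle, and Prl turned to a log2 fold change of -1.62.

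Granule cell markers were lower in the heterozygotes as a group. Of 20 tested members, 19 were lower and 1 higher, with a median log2 fold change of -0.38, -0.32 between the males and -0.38 between the females. No member passed over all genes, and adjusted over the list alone 14 fell and 1 rose. Fat2 had -0.58 ± 0.10 (SE), Gabrd and Gabra6, the delta and alpha6 subunits of the GABA-A receptor found together in granule cells, had -0.56 ± 0.11 and -0.51 ± 0.10 (SE), and Chn2 had -0.47 ± 0.10 (SE). The 1 member that rose was Kcnk9, a leak potassium channel named after its value was seen, with 0.89 ± 0.34 (SE), mostly from the females (1.59 against 0.21 in males). The set test placed the list below other genes (camera, adjusted p = 1.54e-16), which compares genes and does not measure the spread between mice. With an estimated correlation between genes, camera's adjusted p was 0.862. Lists that camera did not call, such as the astrocyte and Bergmann glia list, had the same value, so it cannot decide here.

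Purkinje cell markers were also lower, with 17 of 20 tested members lower and 3 higher and a median log2 fold change of -0.29 (-0.14 in males and -0.39 in females). No member passed over all genes, and 6 fell adjusted over the list alone. Among these were Rora (-0.43 ± 0.10, SE), the nuclear receptor needed for Purkinje cell maturation, Atp2a3 (-0.43 ± 0.11, SE), a calcium pump, Dner (-0.34 ± 0.10, SE), a Notch ligand, and Cacna1g (-0.34 ± 0.10, SE), a T-type calcium channel. The list passed the set test (camera, adjusted p = 6.07e-07; adjusted p = 0.862 with an estimated correlation). The markers of cerebellar GABAergic interneurons went both ways, with 6 of 16 higher and a median of -0.09 although their mean was 0.07 (camera, adjusted p = 0.451), and the median was -0.19 without the male wild type and 0.04 without the female wild type. Adjusted over that list alone, Slc6a5 and Lgi2 (0.91 ± 0.19, SE) rose, though Lgi2 was at 0.36 (adjusted p = 0.0546 in edgeR) without the female wild type and 1.53 without the male wild type, while Slc32a1, the vesicular transporter of GABA and glycine, at 0.30 ± 0.10 (SE), did not pass. The direction of both the granule and the Purkinje list held without the female wild type, which stands apart from the other libraries, with medians of -0.23 and -0.19. Without that library Gabrd was at -0.34 and Atp2a3 at -0.27, and Fat2 was at -0.38 without the male heterozygote.

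Oligodendrocyte and myelin markers were slightly higher, with 19 of 21 higher, a median log2 fold change of 0.15 (0.18 in males and 0.10 in females) and 1 member, the lineage factor Olig1 (0.42 ± 0.10, SE), past the test adjusted over the list alone. Trf, the iron carrier transferrin, had 0.23 ± 0.10 (SE) and did not pass. The set test called the list (camera, adjusted p = 0.0021; adjusted p = 0.862 with an estimated correlation), though not without the male heterozygote (adjusted p = 0.102, median 0.07). The precursor markers (10 tested, median 0.10, adjusted p = 0.738) and the astrocyte and Bergmann glia markers (19 tested, median -0.05, adjusted p = 0.391) were not called by camera. The precursor median was 0.02 without the male wild type and 0.05 without either female library. The astrocyte and Bergmann glia median was -0.09 without the male heterozygote and 0.01 without the female wild type. The microglia markers (19 tested, median 0.18, 0.50 in males and -0.17 in females) were not called either (camera, adjusted p = 0.0983), but were with limma-voom (adjusted p = 0.039). Their median was -0.13 without the male heterozygote, and they were called without the female heterozygote (median 0.42, adjusted p = 1.48e-05) and without the female wild type (median 0.37, adjusted p = 0.00249).

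Endothelial and mural cell markers were lower, with 19 of 20 lower and a median log2 fold change of -0.47. The median was -0.82 in females and -0.07 in males. Slco1a4, a blood-brain barrier transporter, at -0.85 ± 0.16 (SE), and Abcc9, a potassium channel regulator of pericytes, at -0.97 ± 0.26 (SE), fell adjusted over the list alone, while Esam, at -0.55 ± 0.18 (SE), and the other members did not pass. Esam was at -0.30 without the female wild type and -0.79 without the male wild type. The list passed camera (adjusted p = 1.51e-08; adjusted p = 0.862 with an estimated correlation), and its median was -0.18 (adjusted p = 0.0492) without the female wild type and -0.74 without the male wild type. Of 10 listed blood cell markers 4 were tested, with a median of -0.95 (camera, adjusted p = 0.000281; adjusted p = 0.862 with an estimated correlation). Alas2 was the 1 member that fell adjusted over the list alone, and it was at -0.60 without the male wild type. That list lost its call without the male wild type, where the median turned to 0.31, and without the female heterozygote, where the set test turned upward (median -0.35, adjusted p = 0.988). The median was -2.64 without the male heterozygote and -1.47 without the female wild type.

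Markers of tissues that border the cerebellum were higher in the heterozygotes over all libraries, and more clearly so in males. Of 18 choroid plexus markers 15 were higher, with a median log2 fold change of 0.59 that was 0.94 in males and 0.22 in females, and 5 rose adjusted over the list alone. Folr1, a folate receptor, had 1.24 ± 0.28 (SE), F5, coagulation factor V, 1.12 ± 0.30 (SE), and Enpp2, the enzyme autotaxin, 0.46 ± 0.12 (SE). Without the male heterozygote F5 was at 0.50 and Enpp2 at 0.18, and Enpp2 was at 0.72 without the female heterozygote. The list passed camera (adjusted p = 5.62e-07; adjusted p = 0.862 with an estimated correlation) but not without the male heterozygote, where the median was 0.13 and the adjusted p 0.473; without the female heterozygote the median was 0.93. Of 16 meningeal fibroblast markers 13 were higher, with a median of 0.22 that was 0.50 in males but -0.07 in females, and 6 were higher in both sexes (camera, adjusted p = 0.0405; adjusted p = 0.862 with an estimated correlation), and Aldh1a2, a retinoic acid synthesis enzyme, rose adjusted over the list alone (0.81 ± 0.19, SE). That call was lost without the male heterozygote (median 0.07) and without the male wild type (median 0.06), and the median was 0.36 without the female heterozygote and 0.40 without the female wild type.

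Brainstem and midbrain neuron markers were higher on average, with 15 of 25 higher, a median log2 fold change of 0.08 and a mean of 0.41 (camera, adjusted p = 0.000281; adjusted p = 0.862 with an estimated correlation). The median was 0.19 without the male heterozygote and 0.40 without the female wild type, and the call was lost after removal of the trend with transcript length and GC content (median 0.04, adjusted p = 0.0907). Adjusted over the list alone, Th and Dbh, the noradrenaline synthesis enzyme (1.24 ± 0.29, SE), rose, and Hoxa5, a homeobox gene of the caudal hindbrain and spinal cord, fell (-1.20 ± 0.26, SE). Without the female wild type, in a fit that has no sex term, Hoxa5 was at -0.08 (adjusted p = 0.93 in edgeR) and Dbh at 0.50 (adjusted p = 0.0663). Hoxa5 had 328 counts in that library and 90 in the female heterozygote, and 68 in the male wild type and 47 in the male heterozygote, a log2 ratio of -0.81 between the males. Without the male wild type they were at -2.02 and 2.09, and Hoxa5 was at -2.13 without the female heterozygote. Chat, the acetylcholine synthesis enzyme, had 0.81 ± 0.27 (SE) and did not pass. Of 12 tested forebrain neuron markers 8 were higher, with a median of 0.31 (camera, adjusted p = 0.0405; adjusted p = 0.862 with an estimated correlation), and Rgs9, a G-protein regulator of the striatum, had 0.56 ± 0.17 (SE), or 0.31 without the female wild type, with no member past the test over all genes or over the list alone. The forebrain call was lost with limma-voom (median 0.27), without the sex term (median 0.25) and after removal of the length and GC trend (median 0.27, adjusted p = 0.0907), where the median stayed close to its size, and in 3 of 4 fits that left out a library, among them the female wild type, without which the median was 0.04 (adjusted p = 0.162), the male heterozygote (adjusted p = 0.138) and the female heterozygote (adjusted p = 0.152).

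**Figure D2:**
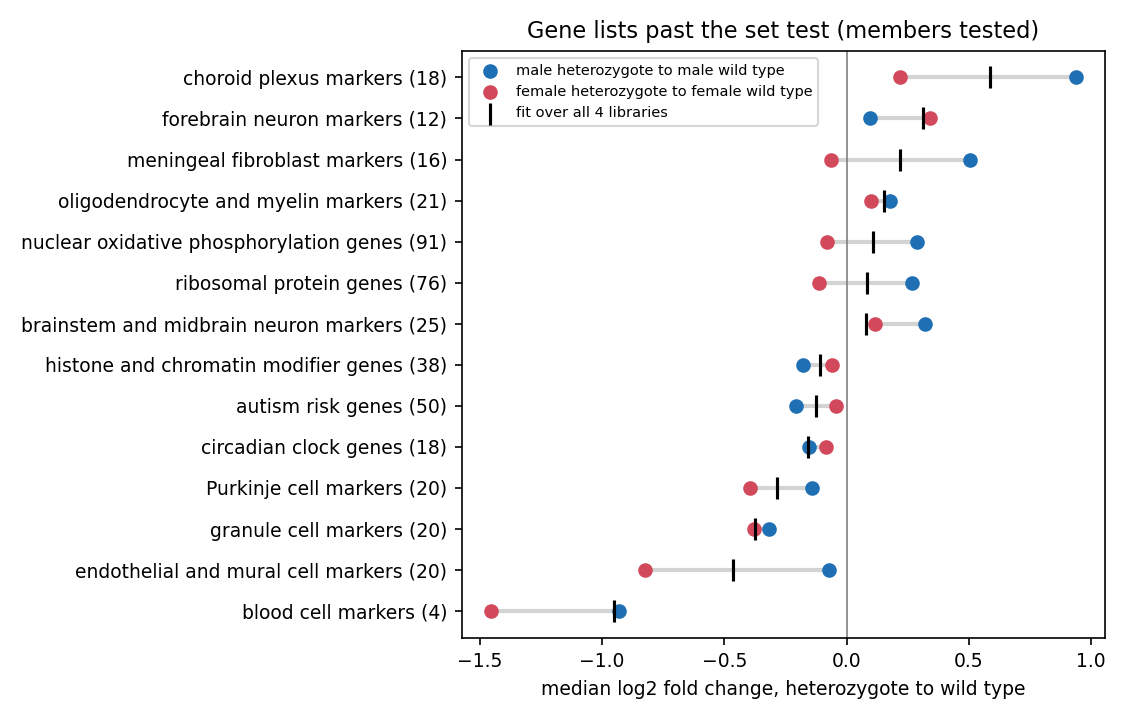
Median log2 fold change of the heterozygote over the wild type (horizontal axis) for the 14 gene lists past the camera set test, with the number of tested members in brackets; blue points compare the males, red points the females and black bars mark the fit over all 4 libraries. The granule cell list lies at -0.32 and -0.38 in the males and females, while the endothelial list lies at -0.07 and -0.82.

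Among the lists of cell functions, circadian clock genes were lower, with 13 of 18 lower and a median log2 fold change of -0.16 (camera, adjusted p = 0.005; adjusted p = 0.862 with an estimated correlation). Nr1d2, a repressor of the clock, fell adjusted over the list alone (-0.41 ± 0.10, SE). Autism risk genes had 35 of 50 lower and a median of -0.13 (camera, adjusted p = 0.00565; adjusted p = 0.862 with an estimated correlation), and Reln alone fell adjusted over the list. Kmt2c, a histone methyltransferase, had -0.36 ± 0.10 (SE), Shank3, a postsynaptic scaffold, -0.33 ± 0.10 (SE), and Dscam, an adhesion molecule, 0.57 ± 0.15 (SE). Shank3 was at -0.19 without the male heterozygote and -0.20 without the female wild type, where Dscam was at 0.29, and Dscam was at 0.86 without the male wild type. Histone and chromatin modifier genes outside the BAF complex had 30 of 38 lower and a median of -0.11 (camera, adjusted p = 0.00448; adjusted p = 0.862 with an estimated correlation), with none past the test singly. Kmt2d had -0.38 ± 0.10 (SE), Chd7 -0.37 ± 0.10 (SE) and Chd3, a remodeller of the NuRD complex, 0.33 ± 0.11 (SE), which was 0.15 without the female wild type and 0.50 without the male wild type. These 3 lists kept their direction but lost the call without the male heterozygote (medians -0.10, -0.09 and -0.06; adjusted p = 0.08, 0.308 and 0.138) and without the male wild type (medians -0.12, -0.08 and -0.13; adjusted p = 0.0513, 0.614 and 0.188). The chromatin modifier median was -0.18 without the female heterozygote.

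Nuclear genes of oxidative phosphorylation (74 of 91 higher, median log2 fold change 0.11; camera, adjusted p = 0.0021) and ribosomal protein genes (63 of 76 higher, median 0.08; camera, adjusted p = 0.0281) were higher over all libraries, with adjusted p = 0.862 for each with an estimated correlation and no member past the test singly. Atp5b, a subunit of the ATP synthase, had 0.23 ± 0.10 (SE). The medians were 0.29 and 0.27 in males but -0.08 and -0.11 in females. Both calls were lost without the male heterozygote (adjusted p = 0.969 and 0.334) and without the male wild type (adjusted p = 0.826 and 0.614). The set test of the ribosomal list turned downward in both fits (medians -0.0315 and 0.00219), and that of oxidative phosphorylation turned without the male wild type (median -0.00641) but not without the male heterozygote (median 0.02). Without the female heterozygote and without the female wild type the medians were 0.17 and 0.20 for oxidative phosphorylation and 0.16 and 0.17 for the ribosomal list. After removal of the trend with transcript length and GC content the ribosomal call was lost (median 0.05; camera, adjusted p = 0.104). That of oxidative phosphorylation was kept (median 0.08; camera, adjusted p = 0.0035).

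The remaining lists were not called by camera, and of the 18 uncalled lists 11 turned in the set test when a library was left out. Immediate early genes had a median of -0.15 (adjusted p = 0.227), with Fos at -0.71 ± 0.20 (SE) and Arc at 0.40 ± 0.13 (SE). Fos was at -0.41 without the female heterozygote and -1.05 without the male heterozygote, and the list's median was -0.03 without the male wild type. Heat shock and protein folding genes had 0.12 (adjusted p = 0.0983), cell cycle genes -0.10 (adjusted p = 0.412), IGF and growth hormone axis genes -0.04 (adjusted p = 0.412), Wnt target genes -0.08 (adjusted p = 0.781), replication-dependent histone genes -0.12 (adjusted p = 0.354) and genes that differ between C57BL/6J and C57BL/6N 0.04 (adjusted p = 0.547). Without the male heterozygote the median was 0.04 for heat shock genes, -0.19 for cell cycle genes and -0.24 for replication-dependent histone genes. Without the female heterozygote it was 0.01 for cell cycle genes, -0.00686 for IGF axis genes and -0.04 for replication-dependent histone genes. Without the male wild type it was 0.00542 for Wnt target genes, -0.25 for replication-dependent histone genes and 0.15 for the substrain genes, which were at -0.07 without the female wild type. Glutamatergic synapse genes had a median of -0.03 and a mean of 0.06 (adjusted p = 0.547). GABAergic synapse genes had 0.04 (adjusted p = 0.61), but adjusted over the list alone Gabrd and Gabra6 fell and Gabra3, another GABA-A receptor subunit, rose (0.66 ± 0.15, SE). Gabra3 was at 0.33 without the female wild type and 1.01 without the male wild type. The GABAergic list's median was 0.09 without the male wild type, -0.02 without the female heterozygote and -0.07 without the female wild type. The glutamatergic list's median was -0.10 without the female heterozygote and 0.02 without the male heterozygote. Protocadherin cluster genes had a median of 0.12 (adjusted p = 0.0983), -0.11 in males and 0.39 in females. They were called by camera without the male heterozygote (median 0.19, adjusted p = 0.00891) and without the male wild type (median 0.31, adjusted p = 0.0466), whereas the median was 0.00322 without the female heterozygote and -0.09 without the female wild type.

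Sex separated the libraries as labelled. Ddx3y, a Y-linked helicase, had 1060 and 877 counts in the males and 1 and 3 in the females, and the Y-linked genes Eif2s3y (663 and 664 against 0 and 2), Kdm5d (467 and 408 against 0 and 0) and Uty (207 and 251 against 0 and 0) followed. Xist, the RNA that silences 1 X chromosome, had 3709 and 8311 counts in the females and 25 and 10 in the males. Outside these, Prl, Mir6236, Hoxb6 and Hoxb8 passed as higher in females, with log2 fold changes of 5.54 ± 0.49, 0.76 ± 0.11, 3.29 ± 0.46 and 4.82 ± 0.71 (SE). Prl was at 2.91 without the female heterozygote and Mir6236 at 0.44 without the male heterozygote. Mir6236 stood at 372 CPM in the male heterozygote, 582 in the male wild type, 696 in the female heterozygote and 886 in the female wild type. Its lowest and highest libraries were also those of the Rn45s share, and a link was not tested. The next gene by p, Hoxa5, did not pass (1.64 ± 0.26, SE; adjusted p = 0.0775). It passed with the likelihood ratio test, DESeq2's size factors, library totals and no filter (adjusted p = 0.00016, 0.0402, 0.0208 and 1.55e-06) and without the female heterozygote (2.33), and was at 0.82 without the female wild type. Hoxb6 and Hoxb8 counts were 126 and 97 in the female wild type and 27 and 16 in the female heterozygote, against 8 or fewer in each male. The genes that escape X inactivation did not pass in edgeR over all libraries, with Kdm6a at 0.61 ± 0.13, Kdm5c at 0.42 ± 0.10, Eif2s3x at 0.50 ± 0.14 and Ddx3x at 0.28 ± 0.12 (SE). Kdm6a passed with no filter (adjusted p = 0.00793) and without the female heterozygote (adjusted p = 0.00471), as did Kdm5c without that library (adjusted p = 0.041). Ddx3x was at 0.12 without the male heterozygote and 0.43 without the male wild type, and Eif2s3x at 0.30 without the male wild type and 0.33 without the female heterozygote.

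In edgeR's quasi-likelihood test 9 genes passed for sex, 5 higher and 4 lower in females. That count was 6 with DESeq2, where Kdm5d, Uty, Hoxb6 and Hoxb8 lost their call, 8 with limma-voom, where Hoxb6 and Hoxb8 did, and 6 under the stricter filter, where Hoxb6, Hoxb8 and Mir6236 did. It was 17 with the likelihood ratio test, 48 with no filter, 5 without the genotype term, 4 without the male heterozygote and 609 without the female heterozygote. The 5 genes higher in females, Xist among them, lost their call without the male heterozygote and without the male wild type, and Mir6236, Hoxb6 and Hoxb8 did so without the female wild type. In the genotype contrast, the list of Y-linked and X-inactivation genes had a median of -0.34 (camera, adjusted p = 0.133) and the escape genes -0.15 (adjusted p = 0.547). The first was called with limma-voom (adjusted p = 0.0242). Fits with a library left out have no sex term, and in them the median of that first list ran from -10.06 to 7.46. The escape gene median was -0.41 without the female heterozygote and -0.27 without the male wild type. It was 0.12 without the male heterozygote and 0.05 without the female wild type.

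The genotype ratios of the males and of the females, which share no library, were weakly related. Across the 15117 tested genes, which are not independent replicates, Pearson's r was 0.176, Spearman's rho 0.238, and 58.4% of genes had the same sign. The female to male ratios within each genotype, as a comparison of the same kind without a shared genotype effect, gave r = -0.0162 and 50.0% of the same sign over the 15108 genes outside the sex lists. With the libraries paired across the sexes instead, Spearman's rho of the genotype ratios was 0.2504 and 59.0% had the same sign. Pairing by sex thus made them no more alike. This largely restates the female to male comparison from the same 4 libraries and is no separate evidence. Granule cell markers lay mostly in the lower left quadrant, with 18 of 20 lower in both sexes. Oligodendrocyte markers lay mostly in the upper right, with 14 of 21 higher in both. Choroid plexus markers spread along the male axis, with 12 of 18 higher in both sexes.

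**Figure D3:**
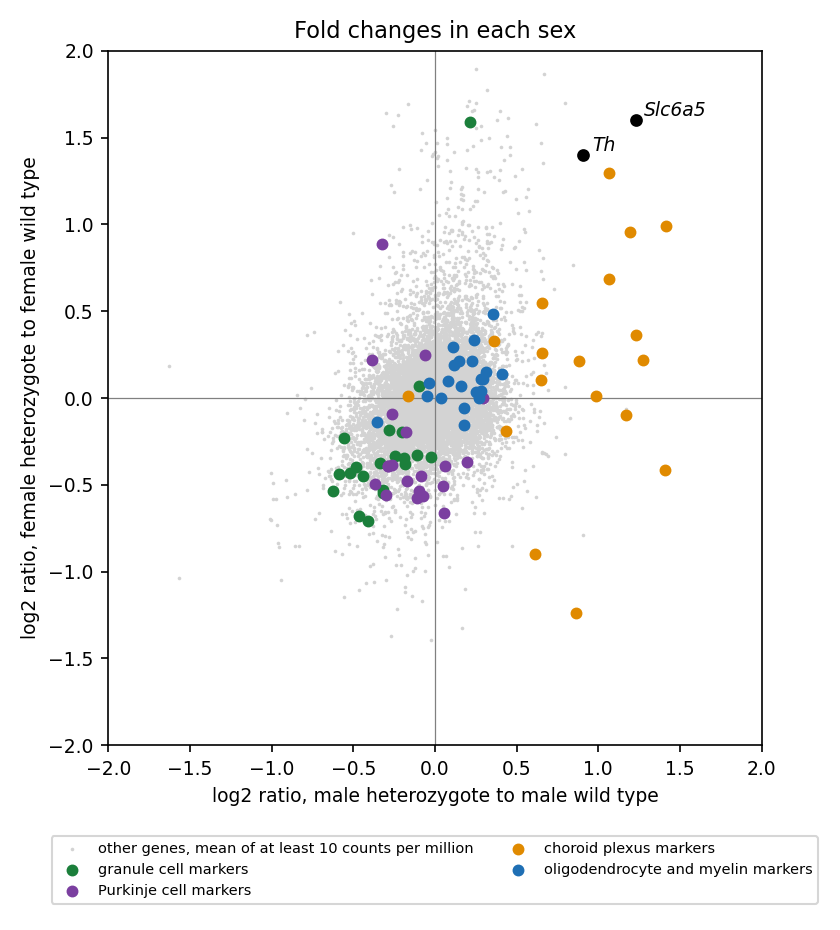
Log2 ratio of heterozygote to wild type in males (horizontal axis) and in females (vertical axis), 1 point per gene; grey points are the 10436 genes with a mean of at least 10 CPM, of which 19 lie outside the axes, and coloured points are 4 marker lists. Granule cell markers gather in the lower left quadrant, and Th (0.91 and 1.40) and Slc6a5 (1.23 and 1.60) lie in the upper right.

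For the difference of the genotype effect between the sexes, 3 genes passed in edgeR's quasi-likelihood test of the product term, 536 genes had an unadjusted p under 0.05, and DESeq2 also called 3 genes, of which 2 were shared. Myh4, a fast myosin heavy chain of skeletal muscle, had 827 counts in the male heterozygote, 0 in the male wild type, 0 in the female heterozygote and 29 in the female wild type (adjusted p = 0.000177). Tnnc2, fast skeletal troponin C, had 358, 0, 9 and 15 counts in the same order (adjusted p = 0.00347). Gh, pituitary growth hormone, had 6, 18, 128 and 1 (adjusted p = 0.0155). Since 4 libraries leave no spare degree of freedom for genotype, sex and their product together, the sex effect served as the residual here.

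The female wild type stood apart from the other 3 libraries. The first principal component of the tested genes held 53.8% of the variance and placed that library at 41.6 and the others between -21.8 and -7.08. Its mean correlation of log2 CPM with the others was 0.979, against 0.984 to 0.985 for the other libraries. Slc6a3, the dopamine transporter, named after its value was seen, had 0 counts in that library, which allows up to 0.146 CPM for counting error alone, against 701 counts in the male heterozygote, 379 in the female heterozygote and 247 in the male wild type.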

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

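In this part, the tests of the female wild type library alone, of the oligodendrocyte and Purkinje medians, and of the midbrain genes one by one, and the fit without the length and GC trend, were chosen only after the result was seen. Results are listed here because a test of the product of genotype and sex called them. Each sex and genotype had a single library, so a difference between the sexes cannot be told apart from a deviation of a single library. The female wild type, which stood apart from the others, enters every female ratio.

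Myh4 (adjusted p = 0.000177), Tnnc2 (adjusted p = 0.00347) and Gh (adjusted p = 0.0155) differed in edgeR's test of the product, each through 1 library. Of the gene lists, 15 differed in the camera test of the product at a preset correlation, and 0 with an estimated one (lowest adjusted p = 0.588). The value of each is the median log2 ratio in females minus that in males. It was negative for endothelial and mural cells (-0.75), choroid plexus (-0.72), microglia (-0.66), meningeal fibroblasts (-0.57), ribosomal proteins (-0.38), replication-dependent histones (-0.38), oxidative phosphorylation (-0.37), cell cycle genes (-0.29), Purkinje cells (-0.25) and astrocytes with Bergmann glia (-0.10). It was positive for protocadherin clusters (0.50), GABAergic synapse genes (0.26), autism risk genes (0.16), chromatin modifiers (0.12) and glutamatergic synapse genes (0.0723).

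The first pattern is transcripts of tissues outside the cerebellum in single libraries. Skeletal muscle carried over at dissection may account for Myh4 and Tnnc2, since 10 other muscle genes, led by Acta1 (774 counts against 29 to 72 elsewhere) and Atp2a1 (598 against 9 to 41), summed in the male heterozygote to 7.90 times the highest other library. For Prl and Gh in the female heterozygote, 7 other pituitary genes summed to 0.783 of the highest other library, within the bound set in advance against pituitary tissue. But 3 of them, Pomc, Tshb and Lhb, had counts in every library. They gave all of that sum apart from 1 count of Cga, which is abundant in that gland. Such a baseline could hide a small share of pituitary tissue, so this source stays open. A residue with only prolactin and growth hormone transcripts stays open too. For Hoxb6 and Hoxb8 in the female wild type, 9 other posterior Hox genes summed to 4.47 times the highest other library, short of the 5 set in advance, so caudal hindbrain or spinal cord tissue cannot be told apart from other sources. For the 0 counts of Slc6a3 in the female wild type, the planned sum of 11 other midbrain dopaminergic genes could not decide between midbrain tissue in the other 3 pieces and other sources (0.910 of the lowest other library), because Aldh1a1, which the cerebellum expresses too, made up 81.0% of it; taken one by one, 10 of the 11 were lowest in that library, but 4 had under 20 counts in every library and 32.4% of all tested genes were lowest there, so this stays open too.

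The second pattern is the lower granule and Purkinje markers in the heterozygotes. For the granule list the female wild type alone is argued against as the source, since the granule median was -0.32 between the male libraries, with 19 of 20 members lower. That comparison has a single library per genotype, and the Purkinje list was not part of it. A lower share of granule cells with every other cell type raised alike would place the oligodendrocyte and Purkinje medians together above 0. They differed by 0.44 (permutation p = 1e-05 over members, two-sided, the smallest that 100000 permutations can give). The Purkinje median was below 0 in both sexes (-0.14 in males and -0.39 in females), which goes against that explanation in these libraries. The permutation shuffled genes and both medians were known beforehand, so its p does not measure the spread between mice. More deep nuclei or brainstem in the dissected pieces of the heterozygotes stays open as a technical explanation. The 9 added genes of projection neurons, among them Glra1 (1.59 ± 0.32, SE) and Nefm (0.36 ± 0.10, SE), had a median of 0.47. All 9 were higher in both sexes. They were chosen after gene results were seen, and Slc17a6 was already in tested lists, so this is weak support. Slc17a6 (0.09 in males, 1.31 in females) and Zcchc12 (0.32, 1.78) rose mostly in females. Sncg (0.66, 0.38), Prph (0.56, 0.13) and Nefh (0.26, 0.17) rose more in males. An effect of the genotype on granule cells, Purkinje cells and projection neurons stays open too and was not tested apart from dissection.

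The third pattern is a trend of the fold changes with transcript length and GC content. Transcript length and GC content explained 2.65% of the variance of the fold changes over genes, but 9.60% in males against 1.61% in females. Spearman's rho of the log2 ratio with length was -0.338 in males and 0.132 in females. These trends of opposite sign partly offset each other over all libraries. After the trend over all libraries was removed, the granule median was -0.36 and the oxidative phosphorylation median 0.0803. The autism risk median was -0.0938 and the chromatin modifier median -0.10. Each had a bootstrap interval without 0. The bootstrap resampled genes, which may vary together, so it does not measure the spread between mice. These values argue against length and GC content as the whole source of the medians over all libraries. They do not exclude a length effect within each sex. In males, where the trend was strongest, the autism risk median went from -0.21 to -0.08, the oxidative phosphorylation median from 0.29 to 0.17 and the chromatin modifier median from -0.18 to -0.10, so part of the male values may come from it. In females the autism risk median went from -0.04 to -0.14 and the chromatin modifier median from -0.06 to -0.16. Both differences between the sexes given above thereby changed sign. The values per sex after removal were centred on the mean of all genes, while those before were not. A shift common to all genes may therefore enter these moves, and the changed signs cannot be credited to length and GC content. The ribosomal median went from 0.08 to 0.0545 (64.1% kept), and this list (adjusted p = 0.104) and the brainstem (46.7% kept) and forebrain (85.6% kept) lists (both 0.0907) were no longer called; for the ribosomal list a length effect and a change of these genes cannot be told apart, and a genotype effect stays open for each list.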

How the results depend on the processing

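The fit after removal of the length and GC trend and the splits of the libraries were chosen after seeing the data. Genotype calls, 3 in the main setting, were 34 with DESeq2 (16 higher, 18 lower), 204 with the likelihood ratio test (96 higher, 108 lower), 7 with DESeq2's size factors, 13 with library totals, 553 with no filter (290 higher, 263 lower), 0 under the stricter filter, 0 without the sex term, 7 at an adjusted p of 0.1 and 3 with limma-voom, and ran from 0 to 2730 with a library left out; the cause was not tested. Genes at p under 0.05, 1766 in the main setting, were 724 with DESeq2 and 400 to 4385 with a library left out. Splitting the 4 libraries in the 3 possible ways gave 1 split with as many genes, the real one (highest other 237), and 3 splits are too few for a share under 0.05. Sex calls, 9 in the main setting, were 17 with the likelihood ratio test, 48 with no filter, 5 without the genotype term and 4 to 609 with a library left out, and the product calls were 6 instead of 3 with no filter. Arid1b kept its direction everywhere (-0.42 to -0.33 with a library left out), and it did not pass 0.05 in any fit that kept all libraries. The 14 called lists were 0 with an estimated correlation and 0 with fry, which missed the call for every list, 7 to 15 with a library left out, 11 after removal of the length and GC trend and 13 to 15 in the other settings at an adjusted p of 0.05; of 18 uncalled lists, 4 were called in some alternative. Among called lists and named genes, directions turned with a library left out for Prl (-1.62 to 6.23), the blood cell list (-2.64 to 0.31), the ribosomal list (-0.0315 to 0.17) and the oxidative phosphorylation list (-0.00641 to 0.20); fewer libraries are part of each such fit. Of the 18 uncalled lists, 11 turned in the set test with a library left out, and the Wnt list also did with no filter. The correlation between the sexes was 0.154 and 0.195 with prior counts of 0.5 and 5 and 0.234 for genes with a mean of at least 10 CPM, where the mean correlation of the female wild type with the others was 0.971. For single named genes in the genotype contrast with all libraries kept, 316 values stayed on their side of the threshold, 103 newly passed it and 6 no longer did, and 7 had no adjusted p in DESeq2 and are not counted. With a library left out these were 127, 81 and 7, and 1 more, Prl, lost its call with its direction turned. Genes with a few counts in a library, such as Prl, Gh and the Hox genes, are limited by depth.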

Other observations

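No test was run for this part, and its genes were chosen after their values were seen. Th stood at 57.8 CPM in the male heterozygote, 51.6 in the female heterozygote, 30.7 in the male wild type and 19.5 in the female wild type. Dbh gave 21.7, 16.7, 13.6 and 4.51 in the same order, Slc6a5 27.2, 17.4, 11.6 and 5.67, and Slc6a3 had 701, 379, 247 and 0 counts. Slc18a2, the vesicular monoamine transporter, gave 42.9, 32.7, 34.3 and 6.98, and Nr4a2, a transcription factor of dopaminergic neurons, 9.32, 8.54, 13.6 and 7.41. Drd2, the D2 dopamine receptor, gave 11.3, 10.8, 7.30 and 2.81, and Chrna6, a nicotinic receptor subunit of dopaminergic neurons, 10.4, 9.11, 5.53 and 0.775.

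Slc17a6, the vesicular glutamate transporter of brainstem and deep nuclear neurons, stood at 163 and 164 CPM in the heterozygotes and 153 in the male wild type, but at 66.3 in the female wild type. Zcchc12 had 129 ± 6.59 CPM in the heterozygotes and 69.6 ± 43.1 in the wild types (mean ± SD, n = 2 each). The hindbrain gene Hoxa5 went the opposite way, with 2.32 CPM in the male heterozygote, 5.65 in the female heterozygote, 4.14 in the male wild type and 15.9 in the female wild type. Mbp, the most abundant transcript in each library, took 0.812%, 0.798%, 0.674% and 0.80% of counts in the male heterozygote, female heterozygote, male wild type and female wild type.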
